A study of Mus musculus with 4 samples.

How the data were processed

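Single-cell RNA-seq libraries were made from dissociated mouse liver non-parenchymal cells, 1 library for each of the groups S, E, HFD_sed and HFD_EXE. Per the labels' protocols, fresh livers were dissociated enzymatically in a gentleMACS device, red blood cells were lysed, dead cells were removed, and 10x Genomics 3′ version 3 libraries were prepared with 5000 to 6000 captured cells per sample. Per the submitters' processing notes, Cell Ranger 6.1.2 and the mouse build GRCm39 were used; the counting options are not given in the sources used here. The deposited matrices hold raw counts of UMIs per gene and barcode, as whole numbers with no normalization. Values came from the matrices of S, HFD_sed and HFD_EXE, and the matrix of E was not analysed here. Between 29 and 46 barcodes were shared by any pair of libraries. The matrices list 55357 gene identifiers paired with 54456 symbols, and counts of identifiers sharing a symbol were summed. Genes are named by these symbols, and no coordinates are given.

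The lowest count in a barcode was 500 UMIs in each of the 3 matrices, so the barcodes had been filtered before deposit. Median UMIs per barcode were 5834, 4031 and 4672, and median detected genes 2298.5, 1783 and 2087, in S, HFD_sed and HFD_EXE. Mitochondrial genes held a median of 3.64%, 3.75% and 3.83% of the UMIs. Cells were kept with at least 500 UMIs, at least 300 genes and under 15% mitochondrial UMIs, which left 10615, 11068 and 10467 cells (91.0%, 94.2% and 92.8%). Doublets were scored per library with Scrublet as built into Scanpy 1.11.5. Its automatic threshold marked 466, 301 and 0 cells. After this was seen, the mean of the automatic thresholds of S and HFD_sed, 0.219, was used for each library. It removed 405, 330 and 294 cells (3.82%, 2.98% and 2.81%), leaving 76847151, 59395524 and 57079531 UMIs in kept cells.

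Kept cells of the 3 libraries were clustered together without integration: counts were scaled per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and Leiden clustering (leidenalg 0.10.2) at resolution 1.0 on 15 nearest neighbours gave 37 clusters. A cluster took the name of a cell type from fixed markers of 24 types, as cells like that type, and needed at least 3 markers detected in a share of at least 0.2 of its cells with a log2 fold of at least 1 over the other cells (pseudocount 0.05 counts per 10000). Clusters where a type of another lineage passed too, with a marker score of at least 0.4 of the best, were called mixed, a rule set after the clusters had been seen. A cluster also stayed unnamed if its 10 leading genes held more markers of another class than of its own. Cluster 14 stayed unnamed because it had too few detected markers of any type. No cell annotation by the authors was used here, so the classes can differ from the study's own. A class was compared where each library had at least 100 of its cells, which gave 10 classes.

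Counts were summed per class and library and divided by the class total to give CPM, with exact Poisson 95% intervals. Log2 ratios between libraries carry an exact conditional binomial interval, and a gene with 0 UMIs was given the bound at 3 counts. Intervals cover counting error only. Cells are not replicates and each group had 1 library, so there was no test between groups, no p-value and no count of changed genes. Before the data were examined, 36 gene lists of 5 to 22 genes (419 genes in all), the marker genes, the comparisons and the rule for naming genes were fixed. A list member was measured where both libraries together held at least 20 of its UMIs in the class, and was called higher or lower where the ratio was at least 1.5 and its interval excluded 1. The median log2 ratio of a list was placed by percentile among 10000 random lists of the same size matched in 20 bins of mean expression, as a description of these libraries, and its 95% interval came from 200 Poisson redraws of the counts of its members. Some genes are on more than 1 list (Dusp1, Per1, Il1b and Cd36 among them), so the lists are not independent. Over all genes of a class, the median log2 ratio of the main comparisons lay within 0.1 of 0, except 0.16 in neutrophils for HFD_EXE over HFD_sed and −0.14 in monocytes for HFD_sed over S.

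For each main comparison and each of the 4 compared classes with the most cells in their smallest library (LSEC, T, Kupffer and B), the rule named the 3 genes per direction whose interval bound nearest to no change was largest. Eligible genes reached 50 CPM in the higher library and at least 0.5 times the level of the whole library there; mitochondrial, ribosomal protein, haemoglobin, antigen receptor, sex-linked, listed hepatocyte and listed erythroid genes and unnamed models were left out. This gave 48 results over the comparisons and classes, for 37 different genes. For each list described, up to 4 members with the largest such bound could be named, besides members that went against the median. Members among the 10 leading genes of a cluster of their class were left out of these. Genes named as leading a cluster and those read as values in the closing section were chosen after their values were seen. The values of some genes that the rule takes are not reported here. Free RNA in a class was estimated from marker genes of other lineages with at least 50 CPM in the whole library. The estimate was the median over these genes of the class level divided by the level of the whole library. That share of the whole-library profile was subtracted in an alternative. A level left under 3 counts was then set to 3 counts, so large ratios in that setting can be bounds and not estimates.

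The alternatives were no doublet removal, a stricter cell filter (1000 UMIs, 500 genes and 10% mitochondrial UMIs), clusters at resolution 0.5 and 2.0, the class of each cell by its highest marker mean, TMM scaling from edgeR 4.0.16 and median-of-ratios scaling without any test, each cell weighted equally, free RNA subtracted, list members with at least 100 UMIs or at least 1 UMI, and shares within immune or non-immune cells. TMM factors lay between 0.945 and 1.06. Added after the data had been seen were a setting without the clusters of a median under 1500 UMIs (4, hepatocytes, and 9, Kupffer cells) and list medians without leading cluster genes. The steps were tested on simulated Poisson counts drawn from the class sums of both libraries together, with 200 genes changed, for the main comparisons in LSECs, T, Kupffer and B cells (8 pairs of a comparison and a class, with 10643 to 14812 genes). The 95% intervals held the true ratio for 95.4% to 96.0% of genes, 4% to 6% of unchanged lists fell in the outer 5% of the percentiles, and the interval lay on the true side of no change for 56% to 78% of genes changed 1.5-fold, 72% to 88% at 2-fold, 90% to 100% at 4-fold and 100% at 8-fold. The simulated draws were independent between genes and held no variation between libraries beyond counting. They therefore do not test the percentiles of lists whose members move together. Python 3.11.15, SciPy 1.17.1, NumPy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3 were used.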

Results

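Droplet-based single-cell RNA sequencing (10x Genomics 3′ chemistry) had been applied to non-parenchymal cells dissociated from the livers of C57BL/6J mice aged 30 weeks, with and without a high fat diet (HFD) and exercise. The labels give 4 groups of 1 library each, named S, E, HFD_sed and HFD_EXE. The endings sed and EXE are read here as without and with exercise, and S as the library whose title names no HFD, since the labels spell out none of these letters. The count matrices of S, HFD_sed and HFD_EXE were analysed, while of E only its 11980 barcodes were used here. The matrices held 11660 barcodes in S, 11752 in HFD_sed and 11280 in HFD_EXE, with 84666844, 63456399 and 60901242 unique molecular identifiers (UMIs, each standing for a captured transcript). The labels state 5000 to 6000 captured cells per sample, fewer than the barcodes of any of these matrices, and do not explain the difference. The number of captures behind a library is therefore not known. After filtering, 10210, 10738 and 10173 cells were kept, with medians of 6148.5, 4178 and 4917 UMIs per cell. Over all kept cells Xist, the transcript of the inactive X chromosome, stood at 0.0651, 0.168 and 0.140 CPM (counts scaled to a common total of UMIs in the cells compared), and the Y-linked Ddx3y at 125, 127 and 151 CPM. With 1 library per group, a library is also an animal or pool, a dissociation and a possible batch, so no difference between groups has a replicate check and none was tested. Values are therefore given side by side, with exact 95% intervals (Poisson for CPM, Clopper-Pearson for shares) that cover counting error only.

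The composition of the cell suspensions differed between the libraries, with liver sinusoidal endothelial cells (LSECs, the fenestrated lining of the sinusoids) and Kupffer cells (the resident liver macrophages) making up less of HFD_sed than of S, and T cells and monocytes more. The LSEC class held 30.1% of S (95% interval 29.2 to 31.0), 22.5% of HFD_sed (21.8 to 23.3) and 49.0% of HFD_EXE (48.0 to 49.998). The Kupffer class held 21.6% (20.8 to 22.4), 7.18% (6.70 to 7.68) and 10.5% (9.94 to 11.1), so that its share in HFD_sed was 3.01-fold lower than in S and that in HFD_EXE 1.47-fold higher than in HFD_sed. Cluster 9, of low UMI counts, held 436 of the 771 Kupffer cells of HFD_sed, and without low-UMI clusters these differences were 6.30-fold and 2.55-fold. The Kupffer class leaves out an unnamed cluster led by Mmp12, with 61, 489 and 89 cells in S, HFD_sed and HFD_EXE. With low-UMI clusters kept, counting these as Kupffer cells would remove the higher share of HFD_EXE over HFD_sed. The share of HFD_sed would stay below that of S. The order of HFD_sed and HFD_EXE among all kept cells therefore depends on how this cluster is named. T cells made up 9.19% (8.63 to 9.76), 25.7% (24.8 to 26.5) and 7.66% (7.15 to 8.19), and monocytes or monocyte-derived macrophages 1.95% (1.69 to 2.24), 11.9% (11.2 to 12.5) and 1.52% (1.29 to 1.78). The T share of HFD_sed was thus 2.79-fold above that of S and 3.35-fold above that of HFD_EXE, and the monocyte share 6.08-fold and 7.78-fold above them.

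Among smaller classes, conventional dendritic cells held 1.16%, 3.21% and 1.06% of the cells of S, HFD_sed and HFD_EXE, and natural killer (NK) cells or type 1 innate lymphoid cells 3.47%, 4.46% and 1.14%. B cells held 6.73%, 9.39% and 4.81%, and neutrophils 6.55%, 4.45% and 6.11%. Vascular endothelium other than LSECs held 1.11%, 1.55% and 2.60%, and its order is not settled. At resolution 2.0 it held 2.97%, 1.58% and 3.86%, and among non-immune cells alone 2.41%, 5.97% and 4.31%. Hepatic stellate cells were 0.304% of S and 0.0983% of HFD_EXE, and 0 of the 10738 cells of HFD_sed, which allows a share of up to 0.0279% (3 counts) for cells classed in this way. That limit depends on the clustering, since HFD_sed had 12 stellate cells (0.112%) at resolution 0.5 and 106 (0.987%) by marker mean. Hepatocytes, which a non-parenchymal preparation is meant to leave out, made up 13.5%, 1.36% and 7.82%. Of the 1382 hepatocytes of S, 1273 lay in the low-UMI cluster 4, and at resolution 2.0 the shares were 1.07%, 0.745% and 2.76%, which turns the order of S and HFD_EXE. Clusters with markers of more than 1 type made up 0.274%, 0.466% and 2.88%, but 7.42%, 4.12% and 2.88% at resolution 0.5. An unnamed cluster numbered 14, led by Mmp12, Mmp13, Cd207, Ms4a7 and Cx3cr1, genes of mononuclear phagocytes, held 0.597%, 4.55% and 0.875%. All shares depend on one another and on the yield of the dissociation. Among non-immune cells alone the LSEC share was 65.6%, 87.1% and 81.4%, which turns the order of HFD_sed against both other libraries. The non-immune cells include the hepatocyte class, with 1382 cells in S but 109 at resolution 2.0. The size of this turn therefore depends on how the low-UMI cells of S are named. Among immune cells alone B cells were at 12.9%, 12.98% and 13.6% and NK cells at 6.63%, 6.17% and 3.22%. There HFD_sed kept the lowest Kupffer share (9.93% against 41.3% in S and 29.8% in HFD_EXE) and the highest T and monocyte shares (35.5% and 16.4%).

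**Figure D1:**
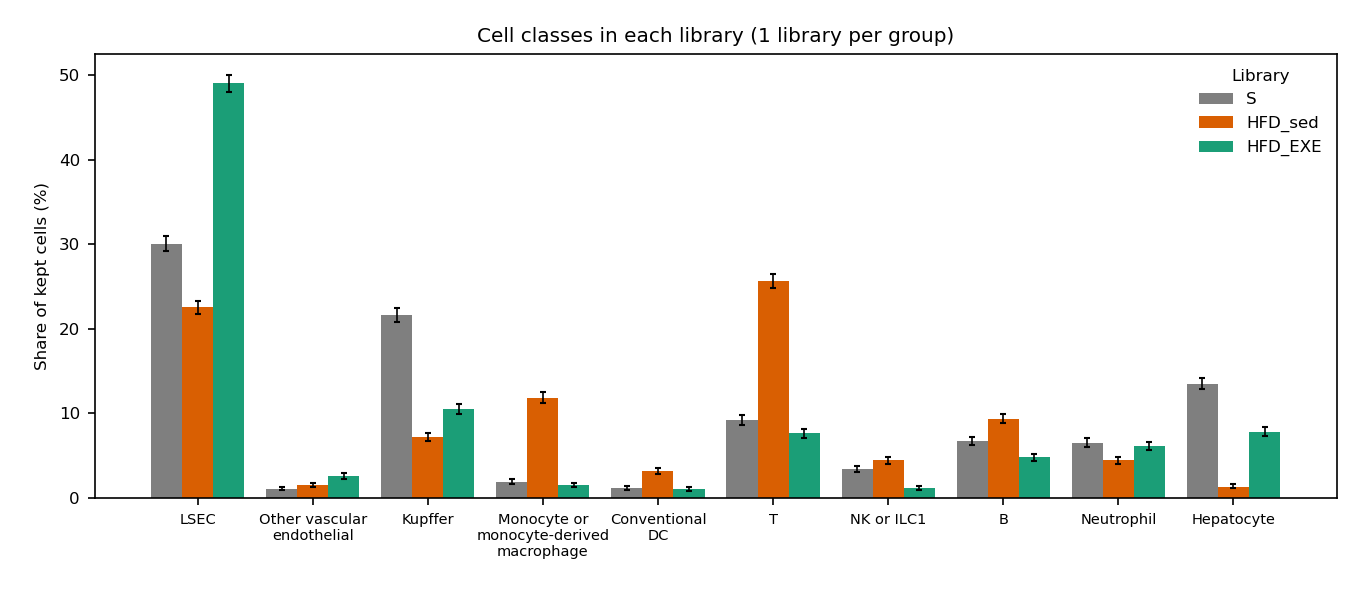
Share of kept cells (%) in 10 cell classes for the libraries S, HFD_sed and HFD_EXE, with exact 95% binomial intervals that cover counting error only. The T bar is at 25.7% in HFD_sed against 9.19% and 7.66%, and the LSEC bar at 49.0% in HFD_EXE against 22.5% in HFD_sed.

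The comparison of HFD_sed with S addresses the diet. In the LSEC class the size rule named the potassium channel subunit gene Kcne3, at 61.7 CPM (57.7 to 65.9) in HFD_sed and 0.408 CPM (0.204 to 0.73) in S, and the membrane glycoprotein gene Gpm6a at 115 CPM (109 to 120) against 1.19 CPM (0.812 to 1.68). In the other direction Ltc4s, the leukotriene C4 synthase, was at 3.65 CPM (2.73 to 4.77) in HFD_sed and 149 CPM (145 to 154) in S. The prostaglandin transporter gene Slco2a1 was at 48.3 CPM (44.7 to 52.0) and 432 CPM (424 to 440). The other genes it named were Depp1, at 638 CPM (625 to 651) and 1.15 CPM (0.781 to 1.63), and Col13a1, at 53.6 CPM and 542 CPM. These lead cluster 2 and cluster 1, which hold most LSECs of HFD_sed and of S, so they describe these clusters. Gpm6a was also among the 10 leading genes of the cluster of other vascular endothelium.

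LSECs of HFD_sed had higher levels of genes of endothelial activation, inflammation and interferon response than those of S, and lower levels of several angiocrine factors, the secreted signals by which the sinusoidal endothelium acts on hepatocytes. Of 14 measured inflammatory cytokine and chemokine genes 13 were higher and 0 lower, with a median log2 ratio of 1.66 (1.56 to 1.77), above all 10000 matched random lists (percentile 100). The monocyte chemoattractant gene Ccl2 was at 40.1 CPM against 4.27 CPM, and Cxcl2 at 35.9 CPM against 6.75 CPM. Cxcl2 stood far higher in monocytes of HFD_sed, so free RNA may contribute to its LSEC values. Of 16 interferon response genes 13 were higher (median 0.83, percentile 100), among them Isg15 at 133 CPM against 33.0 CPM and Ifi44 at 263 CPM against 75.9 CPM. The list of endothelial capillarisation and activation had 8 of 13 members higher and 1 lower (median 0.89, interval 0.56 to 1.04, percentile 100). Its members included P-selectin (Selp), at 39.9 CPM against 5.23 CPM, and apelin (Apln), at 11.6 CPM against 0.148 CPM, while Cd34 was at 6.75 CPM against 13.7 CPM. Immediate early genes, which cells also express on dissociation, had a median of 1.51 with 12 of 13 higher, and heat shock genes a median of 0.60 with 5 of 10 higher. Glycolysis genes had a median of 0.71 with 8 of 13 higher, the glucose transporter gene Slc2a1 being at 13.97 CPM against 1.34 CPM.

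Of 13 angiocrine genes in the LSEC class 7 were lower in HFD_sed and 4 higher, with a median of −0.91 (−0.93 to −0.88) and percentile 0. The Wnt ligands of the central vein region were among the lower ones, Wnt2 at 127 CPM against 496 CPM and Wnt9b at 0.275 CPM against 32.3 CPM, as was hepatocyte growth factor (Hgf) at 41.2 CPM against 161 CPM. At resolution 2.0 a cluster of other vascular endothelium with Wnt9b among its leading genes held 249 cells of S and 37 of HFD_sed. Some of these cells may lie in the LSEC class here, so their placement may contribute to the Wnt9b values. The Notch ligand gene Dll4 was at 161 CPM against 71.7 CPM. LSEC identity genes had a median of −0.27 (percentile 0.45) with 3 of 14 lower, including the hyaluronan receptor gene Stab2 at 785 CPM against 1179 CPM. NRF2 and iron handling genes had a median of −0.37 (percentile 0.13), with 5 of 13 lower and 1 higher, and their member Nqo1, a quinone reductase, was at 1.72 CPM against 29.5 CPM. MHC class II genes had a median of 0.49 with 4 of 8 higher, and hepatocyte transcripts, a marker of free RNA, a median of −0.56 with 10 of 20 lower. With free RNA subtracted the MHC class II median was −2.11, so its direction is not settled. Most LSECs of S were in cluster 1 (led by Cyp26b1 and Col13a1) and most of HFD_sed in cluster 2 (led by Esm1 and Depp1), and a cluster mostly from 1 library may be that library, not a type. In the class of other vascular endothelium the capillarisation list had a median of 0.62 (percentile 99.8), with 6 of 13 higher and 2 lower. The angiocrine list had one of −0.09 (percentile 14.6), with 5 of 13 lower and 2 higher.

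Kupffer cells of HFD_sed had higher levels of lipid-associated macrophage genes, a set that macrophages express in fatty tissue, than those of S. Of 15 measured members 9 were higher and 0 lower, with a median log2 ratio of 1.11 (1.07 to 1.46), above all 10000 random lists (percentile 100). The members with the largest differences were Gpnmb, a glycoprotein gene of lipid-laden macrophages, at 8.11 CPM against 0.367 CPM, the tetraspanin gene Cd63 at 41.9 CPM against 4.17 CPM, the fatty acid binding protein gene Fabp5 at 79.8 CPM against 12.3 CPM and osteopontin (Spp1) at 23.4 CPM against 3.85 CPM. By the size rule, the stress cytokine gene Gdf15 was at 95.1 CPM (84.5 to 107) against 20.2 CPM (18.3 to 22.2), the interferon-induced chemokine gene Cxcl9 at 240 CPM (223 to 258) against 56.3 CPM, and the macrophage elastase Mmp12 at 129 CPM (117 to 143) against 29.9 CPM. Plac8, also a marker on the monocyte list, was at 92.5 CPM (82.0 to 104) against 349 CPM (341 to 357).

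In the same class, Kupffer identity genes had a median of −0.40 (−0.44 to −0.36) with 5 of 12 lower and 1 higher, and scavenging and efferocytosis genes −0.27 with 4 of 13 lower and 1 higher. Alternative activation genes had a median of −0.58 (−0.66 to −0.43), the eotaxin gene Ccl24 being at 185 CPM against 427 CPM and Chil3, which went the other way, at 10.4 CPM against 1.47 CPM. The inflammatory list stood at 0.35 with 5 of 15 higher and 1 lower, the interferon list at 0.25, MHC class II at −0.52, and fatty acid handling at −0.01, although its member Fabp4 was at 349 CPM against 27.7 CPM. Hepatocyte transcripts had a median of −0.71, and the hepatocyte genes Cyp4a14 (4.54 CPM against 66.2 CPM) and Cyp4a10 (4.22 CPM against 56.4 CPM), which encode fatty acid hydroxylases and are not on that fixed list, passed the size rule with them. Kupffer cells had a median of 9208 UMIs in S and 2290 in HFD_sed, and an estimated 15.1% and 32.7% of their UMIs came from free RNA. They lay mostly in cluster 5 in S and in clusters 9 and 10 in HFD_sed. Mmp12 and Gdf15 also led the unnamed cluster 14. With free RNA subtracted the lipid-associated median was 0.43, Fabp5 had a log2 ratio of −0.16, and the inflammatory and scavenging medians turned to −0.071 and 0.0053. Gpnmb and Spp1 stood far higher in monocytes of HFD_sed than in its Kupffer cells, so free RNA may account for their values. Without genes that lead a cluster the identity median was 0.13.

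Monocytes or monocyte-derived macrophages of HFD_sed carried more inflammatory transcripts than those of S, with 12 of 15 members higher and a median of 1.66 (1.57 to 1.77, percentile 100). Tnf was at 172 CPM against 24.2 CPM, the cyclooxygenase gene Ptgs2 at 183 CPM against 15.2 CPM, and Cxcl2 at 1103 CPM against 86.1 CPM. The lipid-associated list had a median of 0.51 (percentile 99.9), with 6 of 15 higher, among them Spp1 at 422 CPM against 25.9 CPM and Cd63 at 173 CPM against 38.8 CPM, and 3 lower. Glycolysis genes had a median of 0.81 with 10 of 13 higher, including Pgk1 at 435 CPM against 191 CPM. Kupffer identity genes (median −1.86) and scavenging genes (median −1.58, the mannose receptor gene Mrc1 at 46.7 CPM against 377 CPM) were lower together with hepatocyte transcripts (median −1.63). Free RNA made up an estimated 33.0% of the monocyte UMIs of S and 9.85% of those of HFD_sed, and with it subtracted the identity and scavenging medians turned to 4.69 and 1.65. These 2 values can rest on levels set to 3 counts, so they leave the direction unsettled. The monocyte class was mostly cluster 21 in S (led by Ace, Krt80 and Eno3) and cluster 8 in HFD_sed (led by Chil3, F13a1 and Fn1). The ratios of this class may therefore reflect which subsets were present, and not only levels within a subset.

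T cells of HFD_sed had higher levels of genes of chronic stimulation, cytotoxicity and chemokine production than those of S, and lower levels of genes of naive and recirculating cells. The macrophage inflammatory protein genes Ccl3 and Ccl4 were at 232 CPM (222 to 242) against 10.7 CPM (8.25 to 13.7), and at 1684 CPM (1658 to 1711) against 130 CPM (121 to 140). Granzyme K (Gzmk) was at 137 CPM (130 to 145) against 6.86 CPM (4.92 to 9.31), a 20.01-fold difference. Of 12 tissue-resident and exhausted T cell genes 8 were higher and 1 lower (median 1.56, interval 1.36 to 1.68, percentile 100). The inhibitory receptor genes Pdcd1 and Lag3 were at 64.2 CPM against 6.53 CPM and 29.0 CPM against 3.35 CPM, and the integrin gene Itgae at 10.6 CPM against 27.5 CPM. Cytotoxic genes had a median of 0.73 with 7 of 11 higher, granzyme A (Gzma) at 272 CPM against 25.4 CPM. The inflammatory list had a median of 1.43 with 10 of 13 higher, the interferon list 0.40 with 7 of 16 higher, and immediate early genes 0.53 with 6 of 13 higher. Of 8 naive genes 5 were lower (median −0.92, interval −0.99 to −0.85, percentile 0), among them the chemokine receptor gene Ccr7 at 118 CPM against 235 CPM.

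The T cell size rule also named Klrb1c, which encodes the NK1.1 receptor and is on the fixed NK marker list, at 25.4 CPM (22.3 to 28.9) in HFD_sed against 126 CPM in S, and the gelatinase gene Mmp9, on the neutrophil marker list, at 20.5 CPM against 106 CPM. The peptide transporter gene Slc15a2 was at 64.8 CPM (59.7 to 70.2) in HFD_sed, against 0 UMIs in S, which allows up to 0.502 CPM (3 counts). The hepatocyte gene Cyp4a14 was at 1.83 CPM against 54.7 CPM beside a hepatocyte list median of −1.22. T cells of HFD_sed were mostly in clusters 7 (led by Cd6, Cd8b1 and Cd8a) and 11 (led by Ctla4 and Cd28). Those of S were mostly in clusters 12 (led by Cxcr6 and Cd28) and 15 (led by Lef1 and Tcf7). The T cell ratios may therefore reflect the mix of subsets, and not only levels within a subset. In the NK class the exhausted list had a median of 0.87 (0.60 to 0.998), with Gzmk at 64.1 CPM against 10.9 CPM. The cytotoxic list had one of −0.13 (percentile 3.18), with Ifng at 129 CPM against 295 CPM. Most NK cells were in cluster 18 in S (led by Gzma and Klra8) and cluster 19 in HFD_sed (led by Gzma, Klra7 and Trdc), so the same limit holds.

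B cells of HFD_sed had more activation transcripts than those of S, with 5 of 11 listed genes higher and a median of 0.73 (0.14 to 0.82, percentile 100). The activation marker gene Cd83 was at 245 CPM against 89.0 CPM and Myc at 113 CPM against 55.1 CPM. Sterol synthesis and uptake genes had a median of 0.51 (0.18 to 0.72) with 4 of 16 higher. Immediate early genes had a median of 0.41 with 5 of 13 higher. By the size rule, Slc15a2 was at 99.6 CPM (89.0 to 111) against 0.346 CPM, Myadm, a myeloid-associated membrane gene, at 234 CPM against 70.3 CPM, and vimentin (Vim) at 643 CPM against 237 CPM. Among the lower genes, Cyp4a14 (3.75 CPM against 77.2 CPM), Cyp4a10 (3.12 CPM against 66.8 CPM) and Serpina3k (25.6 CPM against 141 CPM) are expressed by hepatocytes, whose transcripts had a median of −1.60 in B cells. The inflammatory list stood at 1.40 with 8 of 12 higher, and at −0.24 with free RNA subtracted.

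Neutrophils of HFD_sed had higher levels of inflammatory and NRF2 target genes than those of S. The inflammatory median was 2.46 (2.32 to 2.70), 5.51-fold, with 12 of 14 genes higher. Ccl4 was at 4228 CPM against 414 CPM, Ccl3 at 2096 CPM against 215 CPM and Il1rn, the interleukin-1 receptor antagonist, at 1719 CPM against 216 CPM. The NRF2 and iron handling median was 2.29 (2.16 to 2.41), with 11 of 13 higher and 1 lower, the glutathione synthesis gene Gclc being at 176 CPM against 11.04 CPM and Nqo1 at 54.9 CPM against 3.36 CPM. Glycolysis genes had a median of 0.95 with 8 of 13 higher, Pgk1 at 282 CPM against 102 CPM. The activation list was split, with 6 higher and 5 lower of 15 and a median of −0.11. Its granule genes Camp and Ltf were at 278 CPM against 5.76 CPM and 224 CPM against 10.6 CPM. Hepatocyte transcripts had a median of −1.56, and the class was mostly cluster 6 in S and, in HFD_sed, mostly cluster 22, which is itself led by Cxcl2, Ptgs2 and Slc7a11.

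Over the 9 compared classes other than hepatocytes, the inflammatory list median was higher in HFD_sed than in S in 9, from 0.33 (−0.072 to 0.65) in NK cells to 2.46 in neutrophils, with conventional dendritic cells at 0.81 and other vascular endothelium at 1.24. It was higher in 6 with free RNA subtracted, and stood at −0.24 in B cells, −0.071 in Kupffer cells and −0.22 in NK cells. Heat shock genes, which cells also express on handling, had medians above 0 in the 9 classes, from 0.23 in NK cells to 0.60 in LSECs. ER stress genes did too, from 0.14 (−0.010 to 0.32) in Kupffer cells to 0.94 in monocytes. Erythroid transcripts, which mark other cells or free RNA, were higher in HFD_sed than in S in 8 of the 8 classes where measured. Their medians ran from 0.88 in LSECs to 4.19 in neutrophils, without subtraction of free RNA. The glucocorticoid response list was higher in 7 classes and lower in 2, from −0.47 in NK cells to 0.68 in LSECs, but this count depends on the setting. Monocytes turned from −0.28 to 0.55 with free RNA subtracted, and neutrophils from 0.34 to −0.11 without doublet removal. Its LSEC members went both ways, with 6 of 11 higher, among them the clock gene Per1 at 59.1 CPM against 13.8 CPM, and 3 lower, among them the metallothionein gene Mt2 at 116 CPM against 339 CPM.

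The comparison of HFD_EXE with HFD_sed addresses exercise under the diet. In the LSEC class Edn1, which encodes the vasoconstrictor endothelin-1 and also leads the cluster of other vascular endothelium, was at 1.34 CPM (0.956 to 1.82) in HFD_EXE and 104 CPM (98.9 to 109) in HFD_sed, 77.7-fold lower. Ednrb, the endothelin receptor type B, was at 266 CPM (260 to 272) against 6.26 CPM (5.04 to 7.69), 42.5-fold higher. The levels in S were 1.93 CPM for Edn1 and 35.5 CPM (33.3 to 37.9) for Ednrb. Mup11, a major urinary protein gene of hepatocytes that is not on the fixed hepatocyte list, was at 56.2 CPM (53.5 to 58.9) against 2.13 CPM (1.45 to 3.03). It was at 1627 CPM in the hepatocyte class of HFD_EXE against 61.1 CPM in that of HFD_sed. Of the other genes the size rule named, Gja4 leads cluster 0, which holds most LSECs of HFD_EXE, and Depp1 and Esm1 lead cluster 2, which holds most of those of HFD_sed, so they describe these clusters.

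LSECs of HFD_EXE had lower levels of inflammatory, interferon, MHC class II and endothelial activation genes than those of HFD_sed, and higher levels of angiocrine and glucocorticoid response genes. Of 15 inflammatory genes 12 were lower and 1 higher, with a median log2 ratio of −1.22 (−1.40 to −1.13), a 2.33-fold difference below all 10000 random lists (percentile 0). Ccl2 was at 3.78 CPM against 40.1 CPM and Ccl4 at 10.0 CPM against 52.3 CPM, while Nfkbia, which encodes an inhibitor of NF-κB, was at 851 CPM against 409 CPM. Ccl4 stood far higher in T cells and neutrophils of HFD_sed, so free RNA may account for its LSEC values. The interferon list had a median of −0.93 (−0.97 to −0.84) with 13 of 16 lower, Isg15 at 29.2 CPM against 133 CPM. MHC class II genes had a median of −1.15 (−1.20 to −1.08) with 6 of 8 lower, the invariant chain gene Cd74 at 98.6 CPM against 219 CPM. Free RNA may supply part of the HFD_sed level, since the HFD_sed over S median of this list was −2.11 with it subtracted. The capillarisation list had a median of −1.05 (−1.31 to −0.84) with 10 of 13 lower, Selp at 2.38 CPM against 39.9 CPM, and 1 higher, Cd34 at 16.1 CPM against 6.75 CPM. Immediate early genes stood at −1.05 with 10 of 13 lower, among them Egr1 at 254 CPM against 945 CPM, heat shock genes at −0.44 with 2 of 10 lower, and glycolysis genes at −0.55 with 6 of 13 lower.

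Angiocrine genes in the same LSECs had a median of 0.68 (0.65 to 0.71) with 7 of 13 higher and 3 lower. Wnt9b was at 11.5 CPM against 0.275 CPM and Hgf at 211 CPM against 41.2 CPM, while Dll4 was at 26.6 CPM against 161 CPM. The cluster with Wnt9b among its leading genes at resolution 2.0 held 343 cells of HFD_EXE and 37 of HFD_sed. The placement of these cells may contribute here too. LSEC identity genes had a median of 0.32 (percentile 99.4) with 2 of 14 higher, among them the lymphangiogenic receptor gene Flt4 at 1141 CPM against 710 CPM, and NRF2 genes 0.37 with 3 of 13 higher and 1 lower. Of 11 glucocorticoid response genes 9 were higher and 0 lower, with a median of 1.32 (1.25 to 1.43), 2.49-fold. Klf9, a transcription factor gene induced by the glucocorticoid receptor, was at 968 CPM against 282 CPM, Zbtb16 at 5.46 CPM against 0.482 CPM and Mt2 at 566 CPM against 116 CPM. Hepatocyte transcripts had a median of −0.04 (percentile 57.7). In the class of other vascular endothelium the capillarisation median was −0.995 (−1.25 to −0.88) with 9 of 13 lower, Apln at 1.03 CPM against 28.7 CPM. The angiocrine median there was 1.07 (0.99 to 1.13) with 8 of 13 higher and 3 lower, Bmp2 at 1955 CPM against 325 CPM. LSEC identity genes and platelet transcripts in this class had medians of 0.62 and 1.36 (percentiles 99.96 and 99.84). Other cells or their RNA may therefore contribute to its values.

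**Figure D2:**
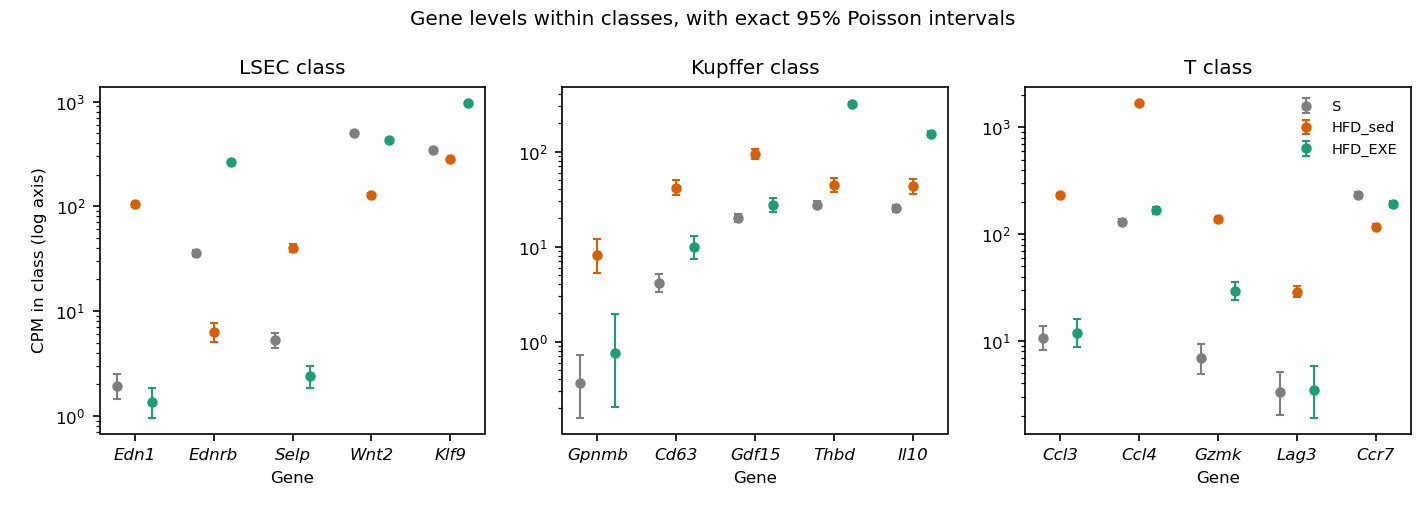
CPM (log axis) of 5 genes each in the LSEC, Kupffer and T cell classes for the libraries S, HFD_sed and HFD_EXE, without subtraction of free RNA, 1 point per library with its exact 95% Poisson interval. Edn1, Selp, Gpnmb, Ccl3 and Lag3 stand highest in HFD_sed, and Ednrb, Klf9, Thbd and Il10 in HFD_EXE, as with Ednrb at 266 CPM in LSECs.

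Kupffer cells of HFD_EXE had lower levels of lipid-associated macrophage genes than those of HFD_sed. The lipid-associated list had a median of −0.43 (−0.48 to −0.37), with 7 of 14 lower and 0 higher, Gpnmb at 0.758 CPM against 8.11 CPM, Cd63 at 9.85 CPM against 41.9 CPM and the integrin gene Itgax at 5.30 CPM against 20.4 CPM. Gpnmb stood far higher in monocytes of HFD_sed, a class with a smaller share in HFD_EXE, so free RNA may account for its values. The inflammatory list had a median of −0.55 (−0.71 to −0.42), but 0.20 with free RNA subtracted, so its direction is not settled. Of its 15 members 7 were lower, interleukin-1β (Il1b) at 307 CPM against 963 CPM and Ccl3 at 45.5 CPM against 182 CPM, and 1 higher, Il6 at 42.8 CPM against 22.7 CPM. By the size rule, thrombomodulin (Thbd), an anticoagulant cofactor, was at 313 CPM (298 to 328) against 44.8 CPM (37.6 to 52.9). The lower genes were Asb2, part of a ubiquitin ligase, at 1.89 CPM (0.908 to 3.48) against 58.1 CPM (49.9 to 67.2), Irak3, a brake on Toll-like receptor signalling, at 13.1 CPM against 70.1 CPM, and the glutamate transporter gene Slc1a2 at 11.6 CPM against 57.4 CPM. Alternative activation genes had a median of 0.45 (0.28 to 0.62) with 4 of 10 higher and 1 lower, interleukin-10 (Il10) being at 153 CPM against 43.1 CPM.

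Kupffer glucocorticoid response genes had a median of 1.69 (1.56 to 1.79), 3.22-fold, with 6 of 10 higher, Klf9 at 375 CPM against 87.6 CPM and the cell cycle inhibitor gene Cdkn1a at 262 CPM against 54.8 CPM. Fatty acid handling genes had a median of 0.26 with 5 of 16 higher and 2 lower, the pyruvate dehydrogenase kinase gene Pdk4 at 22.4 CPM against 5.19 CPM and Fabp4 at 147 CPM against 349 CPM. Scavenging genes had a median of 0.13 (percentile 87.8) with Gas6 at 87.1 CPM against 27.3 CPM. Kupffer identity genes (0.04, percentile 59.4), interferon genes (0.04, percentile 54.3) and MHC class II genes (−0.08, percentile 21.2) lay within the bulk of the random lists. Hepatocyte transcripts stood at 0.55 with 9 of 18 higher, and Mup11 (87.0 CPM against 2.92 CPM) and Serpina1e (71.8 CPM against 5.52 CPM), which hepatocytes express, passed the size rule with them. The Kupffer class had a median of 3628 UMIs in HFD_EXE and 2290 in HFD_sed, with an estimated 26.0% and 32.7% from free RNA, and was mostly cluster 10 in HFD_EXE. With free RNA subtracted the identity median turned to −0.081 and the hepatocyte median to −0.30, and the lipid-associated median ranged from −0.52 to −0.20 over all alternatives run.

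Monocytes or monocyte-derived macrophages of HFD_EXE had lower levels of lipid-associated, inflammatory and glycolysis genes than those of HFD_sed, and higher levels of scavenging genes. The lipid-associated median was −0.63 (−0.73 to −0.39) with 7 of 15 lower, Gpnmb at 15.6 CPM against 141 CPM and Spp1 at 127 CPM against 422 CPM, and 1 higher, the fatty acid transporter gene Cd36 at 389 CPM against 150 CPM. The inflammatory median was −0.94 (−1.28 to −0.78) with 10 of 15 lower, Il1b at 417 CPM against 1563 CPM, and the glycolysis median −0.82 with 7 of 13 lower, the hexokinase gene Hk2 at 39.1 CPM against 132 CPM. Scavenging genes had a median of 0.88 (0.74 to 1.40) with 7 of 13 higher, Mrc1 at 268 CPM against 46.7 CPM. Kupffer identity genes stood at 0.62 (0.08 to 0.90) and hepatocyte transcripts at 1.05, and with free RNA subtracted both were at −0.37. Free RNA made up an estimated 18.5% of the monocyte UMIs of HFD_EXE and 9.85% of those of HFD_sed. It may therefore contribute to the higher scavenging values. The class was mostly cluster 8 in both libraries, with 1102 cells of HFD_sed and 95 of HFD_EXE. Cluster 21 held 171 and 60, a larger share of the class in HFD_EXE. The mix of subsets may therefore contribute to these monocyte ratios.

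T cells of HFD_EXE had lower levels of exhaustion, cytotoxicity and chemokine genes than those of HFD_sed, and higher levels of naive cell genes. Ccl3 was at 12.0 CPM (8.84 to 15.9) against 232 CPM (222 to 242), Ccl4 at 168 CPM (156 to 182) against 1684 CPM (1658 to 1711), and Slc15a2 at 1.25 CPM against 64.8 CPM. The exhausted list had a median of −1.62 (−1.67 to −1.26), 3.07-fold, with 9 of 12 lower, among them Lag3 at 3.50 CPM against 29.0 CPM and Gzmk at 29.5 CPM (24.4 to 35.3) against 137 CPM. The cytotoxic median was −0.63 (−0.83 to −0.55) with 6 of 11 lower, Gzma at 31.0 CPM against 272 CPM, and 1 higher. Naive genes had a median of 0.80 (0.68 to 0.85) with 5 of 8 higher. The inflammatory median was −1.23 (−1.86 to −1.06) with 11 of 13 lower and 1 higher, the interferon median −0.48 with 6 of 16 lower, and the immediate early median −0.81 with 8 of 13 lower. Glucocorticoid response genes had a median of 0.73 (0.61 to 0.96) with 7 of 11 higher, Klf9 at 113 CPM against 37.8 CPM.

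The T cell size rule further named Klrb1c at 166 CPM (153 to 179) against 25.4 CPM, Serpina3f, a serine protease inhibitor gene, at 241 CPM (226 to 256) against 46.6 CPM, and the interleukin-12 receptor gene Il12rb2 at 55.7 CPM against 10.1 CPM. Hepatocyte transcripts had a median of 0.46 in T cells, and −0.039 with free RNA subtracted. The T cells of HFD_EXE were mostly in clusters 12 and 13, unlike those of HFD_sed. The mix of subsets may therefore contribute to these T cell ratios and to those of the NK class. In the NK class, with 116 cells in HFD_EXE, mostly in cluster 18, the exhausted list had a median of −0.68 with 5 of 9 lower and 2 higher, Gzmk at 5.19 CPM against 64.1 CPM but Pdcd1 at 53.6 CPM against 14.6 CPM. The cytotoxic list had a median of −0.24.

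B cells of HFD_EXE had higher Fkbp5, a glucocorticoid-induced co-chaperone gene, at 117 CPM (102 to 134) against 24.7 CPM, and higher Ddit4, an inhibitor of mTOR signalling, at 95.8 CPM against 25.3 CPM. Rgs2, a regulator of G protein signalling, was at 98.0 CPM against 335 CPM, the kinase gene Plk2 at 49.0 CPM against 162 CPM, and Slc15a2 at 0 UMIs, which allows up to 1.65 CPM, against 99.6 CPM. Activation genes had a median of −0.37 (−0.44 to −0.15) with 4 of 11 lower, Cd83 at 104 CPM against 245 CPM, immediate early genes −0.83 with 10 of 13 lower, and sterol genes −0.01 with 0 of 15 higher or lower. Mup11 was at 66.6 CPM against 1.25 CPM beside a hepatocyte list median of 0.54. The B cell inflammatory median of −1.56 and glucocorticoid median of 0.97 turned to 0.092 and −0.26 with free RNA subtracted.

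Neutrophils of HFD_EXE had lower levels of inflammatory and NRF2 target genes than those of HFD_sed. The inflammatory median was −1.41 (−1.84 to −1.23) with 12 of 14 lower, Tnf at 40.8 CPM against 622 CPM and Ccl4 at 249 CPM against 4228 CPM. The NRF2 median was −1.80 (−2.03 to −1.65) with 11 of 13 lower and 1 higher, Gclc at 19.4 CPM against 176 CPM and Nqo1 at 3.06 CPM against 54.9 CPM. Glycolysis genes had a median of −0.94 with 8 of 13 lower and 1 higher, Hk2 at 10.2 CPM against 39.8 CPM. The activation list had 5 of 15 higher and 6 lower (median −0.24, percentile 8.82), Camp being at 48.4 CPM against 278 CPM and Mmp8 at 737 CPM against 266 CPM. Hepatocyte transcripts stood at 0.80, and neutrophils of HFD_EXE were mostly in cluster 6.

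Over the 9 compared classes other than hepatocytes, the inflammatory list median was lower in HFD_EXE than in HFD_sed in 9, from −1.86 in other vascular endothelium to −0.36 in conventional dendritic cells, at percentiles of 0 to 0.08. It was lower in 7 with free RNA subtracted, and stood at 0.092 in B cells and 0.20 in Kupffer cells. Heat shock medians were below 0 in the 9 classes, from −0.82 in NK cells to −0.18 in other vascular endothelium. The glucocorticoid list median was higher in 9, from 0.73 in T cells to 1.87 in other vascular endothelium, where Cdkn1a was at 427 CPM against 109 CPM and Mt1 at 1138 CPM against 212 CPM, and each lay above all 10000 random lists (percentile 100). With free RNA subtracted the median was above 0 in 8, B cells being at −0.26, and percentiles were not computed in that setting. Monocytes stood at 1.33, NK cells at 1.43, dendritic cells at 1.23 and neutrophils at 0.94 for this list, with Fkbp5 at 230 CPM against 46.1 CPM in neutrophils. In the dendritic cells the inflammatory median was 0.037 with clusters at resolution 0.5. Lists that mark other cells or the state of the cells differed as well. Erythroid medians of HFD_EXE over HFD_sed ran from −0.19 in T cells to 5.71 in NK cells (percentile 100), and their direction is not settled in 5 classes. With free RNA subtracted B cells turned from 0.33 to −2.86 and LSECs from 0.87 to −5.90, values that can be bounds. By marker mean dendritic cells turned from 1.56 to −0.54 and T cells to 0.21, which were at 0.46 without doublet removal. Neutrophils turned from 0.070 (−0.046 to 0.17) to −0.091 with TMM scaling. Mitochondrially encoded genes had medians above 0 in 9, from 0.00025 (−0.13 to 0.023) in other vascular endothelium to 0.62 in monocytes (percentile 100).

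**Figure D3:**
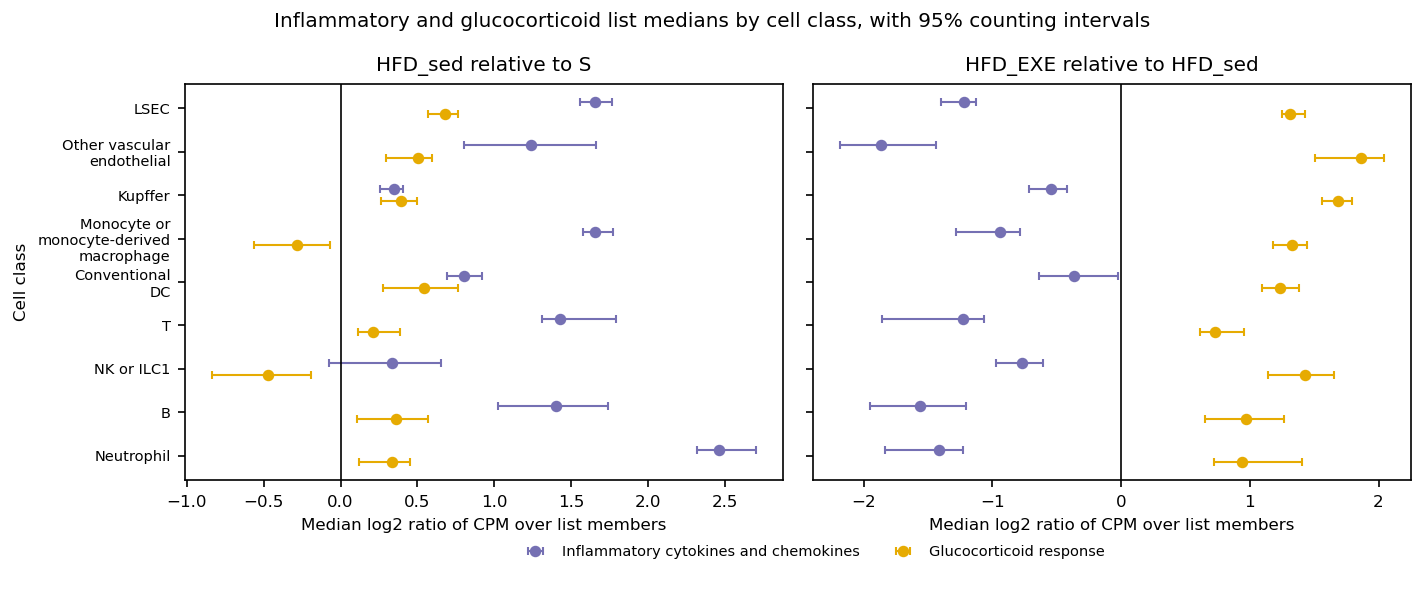
Median log2 ratio of CPM over the members of the inflammatory and glucocorticoid lists in 9 cell classes, for HFD_sed relative to S and HFD_EXE relative to HFD_sed, without subtraction of free RNA, with 95% intervals that cover counting error only and a line at 0. Inflammatory medians run from 0.33 to 2.46 in the HFD_sed panel and from −1.86 to −0.36 in the HFD_EXE panel, where glucocorticoid medians run from 0.73 to 1.87.

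HFD_EXE and S are set side by side as values, since this comparison shares both libraries with the others. The genes were picked from those named above and do not stand for all genes. LSEC levels in HFD_EXE and S were 428 and 496 CPM for Wnt2, 11.5 and 32.3 CPM for Wnt9b, 211 and 161 CPM for Hgf, 415 and 432 CPM for Slco2a1, 29.2 and 33.0 CPM for Isg15, and 3.78 and 4.27 CPM for Ccl2. Ltc4s was at 50.3 and 149 CPM, Klf9 at 968 and 345 CPM, and Egr1 at 254 and 157 CPM. In T cells Ccl4 was at 168 and 130 CPM, Lag3 at 3.50 and 3.35 CPM, and Klf9 at 113 and 33.8 CPM. In Kupffer cells Gpnmb was at 0.758 and 0.367 CPM, Fabp5 at 46.4 and 12.3 CPM, Cd63 at 9.85 and 4.17 CPM, Thbd at 313 and 27.6 CPM, and Klf9 at 375 and 93.5 CPM. T cells of both libraries shared cluster 12 as their largest cluster, while most LSECs of HFD_EXE were in cluster 0 and most of S in cluster 1. Over the 9 classes the inflammatory median of HFD_EXE over S was above 0 in 6, from −0.27 in NK cells to 0.83 in monocytes (percentile 100), with LSECs at 0.18 but −0.92 with free RNA subtracted. The glucocorticoid median was above 0 in 9, from 0.44 in B cells to 1.72 in Kupffer cells, and the ER stress median in 9, from 0.018 (−0.13 to 0.19) in NK cells to 0.70 in monocytes. Kupffer identity genes had a median of −0.41 in Kupffer cells and −0.77 in monocytes, and there 3.96 with free RNA subtracted, which can be a bound. Erythroid medians of HFD_EXE over S, without that subtraction, were above 0 in 9 classes, from 1.59 in T cells to 6.87 in NK cells.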

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

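The settings without low-UMI clusters and without leading cluster genes were chosen after seeing the data. With 1 library per group, leaving out a replicate was not possible, and no paired analysis was possible because no libraries are paired. Values below are log2 ratios unless given in %, first for HFD_EXE over HFD_sed and then for HFD_sed over S, with the reported value in brackets. Where a value moved beyond its counting interval or turned its sign, the cause was not tested, except where the setting itself sets the denominator.

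The 48 results of the size rule kept their direction in all 480 values under the alternatives. Of 992 values for 100 list members named in the text, 991 kept it, the exception being Fabp5 in Kupffer cells (2.70), at −0.16 with free RNA subtracted. Values with both levels at or under 3 counts, which can occur once free RNA is subtracted, had no ratio and are not counted here. Of 475 member results the rule could take, 26 of 4713 values were reversed. Of 1365 values for lists whose interval excludes 0, 1338 kept their direction, and of 752 for lists given only over classes or for HFD_EXE over S, 746. Shares kept it in 133 of 140. TMM and median-of-ratios scaling turned none of the gene and list values reported whose interval excludes 0. Hepatocyte genes in other classes, such as Mup11 in B cells and Cyp4a14 in T cells, kept their direction with free RNA subtracted too. That setting may thus leave free RNA behind, and a direction kept in it does not exclude free RNA.

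Counted within immune or non-immune cells, the shares of HFD_EXE over HFD_sed were 0.065 for B cells (−0.97), −0.10 for LSECs (1.12) and −0.47 for other vascular endothelium (0.75), all turned, and 1.58 for Kupffer cells (0.55), −1.93 for monocytes (−2.96) and −0.71 for T cells (−1.74). For HFD_sed over S they were 0.41 for LSECs (−0.42) and −0.10 for NK cells (0.36), both turned, and −2.06 for Kupffer cells (−1.59), 2.14 for monocytes (2.60) and 1.01 for T cells (1.48). The change of denominator accounts for these, and for LSECs and other vascular endothelium it includes the hepatocyte class. The Kupffer share moved to 0.85 with the stricter filter, 1.28 at resolution 0.5 and 1.35 without low-UMI clusters, and for HFD_sed over S to −2.02, −2.49 and −2.65 in these settings, −1.30 at resolution 2.0 and −1.76 by marker mean. The LSEC share moved to 1.27 at resolution 0.5, 1.01 at 2.0 and 1.36 by marker mean, and for HFD_sed over S to −0.75, −0.71 and −0.84, with −0.82 without doublet removal and −0.61 without low-UMI clusters. The T share moved to −1.87 by marker mean, and for HFD_sed over S to 1.37 with the stricter filter and 1.28 without low-UMI clusters. The share of other vascular endothelium for HFD_sed over S (0.48) turned to −0.91 at resolution 2.0 and −0.83 by marker mean. Of the shares of stellate cells, hepatocytes and mixed clusters per library, 37 of 57 values moved beyond their intervals, such as hepatocytes of S (13.5%) at 1.29% without low-UMI clusters.

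Subtracting free RNA reversed 16 medians of the lists described by class, counting those whose interval excludes 0. For HFD_EXE over HFD_sed these were the B cell inflammatory (0.092, from −1.56) and glucocorticoid lists (−0.26, from 0.97), and in Kupffer cells the identity (−0.081, from 0.04), inflammatory (0.20, from −0.55), MHC class II (0.25, from −0.08) and hepatocyte lists (−0.30, from 0.55). The monocyte Kupffer identity (−0.37, from 0.62) and hepatocyte lists (−0.37, from 1.05) and the T cell hepatocyte list (−0.039, from 0.46) turned as well. For HFD_sed over S they were the B cell inflammatory (−0.24, from 1.40), Kupffer inflammatory (−0.071, from 0.35), Kupffer scavenging (0.0053, from −0.27) and LSEC MHC class II lists (−2.11, from 0.49), and in monocytes the Kupffer identity (4.69, from −1.86), scavenging (1.65, from −1.58) and glucocorticoid lists (0.55, from −0.28). Of the others, it reversed the erythroid list for HFD_EXE over HFD_sed in B cells (−2.86, from 0.33) and LSECs (−5.90, from 0.87), and the monocyte Kupffer identity list for HFD_EXE over S (3.96, from −0.77). Large values in this setting can rest on levels set to 3 counts. Medians whose interval includes 0 turned too, among them the inflammatory list in NK cells for HFD_sed over S (−0.22, from 0.33) and in LSECs for HFD_EXE over S (−0.92, from 0.18). The LSEC inflammatory list moved to −1.66 (−1.22) and for HFD_sed over S to 1.34 (1.66).

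Of the other settings, resolution 0.5 turned the dendritic cell inflammatory list (0.037, from −0.36), Kupffer identity (−0.092) and Kupffer MHC class II (0.095). Without low-UMI clusters Kupffer identity and MHC class II were −0.093 and 0.093. Kupffer identity was −0.017 without doublet removal, −0.0035 with the stricter filter and −0.59 without leading cluster genes. For HFD_sed over S it turned to 0.13 (−0.40) without leading genes. The erythroid list was −0.54 in dendritic cells (1.56) by marker mean, and in T cells (−0.19) 0.21 by marker mean and 0.46 without doublet removal. By marker mean the monocyte Kupffer identity list was −0.53, and without doublet removal the neutrophil glucocorticoid list for HFD_sed over S was −0.11 (0.34).

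The Kupffer lipid-associated list (−0.43) was −0.29 without doublet removal, −0.23 at resolution 0.5 and without low-UMI clusters, −0.52 by marker mean, −0.34 with free RNA subtracted, −0.20 with at least 100 UMIs and −0.28 without leading genes. For HFD_sed over S (1.11) it was 0.95 at resolution 0.5 and without low-UMI clusters, 2.22 with each cell weighted equally and 0.43 with free RNA subtracted. The LSEC inflammatory list was −1.11 by marker mean, and for HFD_sed over S 1.90 with at least 100 UMIs and 1.41 with at least 1. The LSEC capillarisation list (−1.05) was −0.81 without leading genes, and for HFD_sed over S (0.89) 1.07 at resolution 2.0. The T cell exhausted list for HFD_sed over S (1.56) was 1.72 with each cell weighted equally, 1.32 with at least 100 UMIs and 1.92 without leading genes. The LSEC glucocorticoid list ranged from 1.29 to 1.37, and for HFD_sed over S from 0.60 to 0.71. Depth limits genes with few UMIs, stellate cells and small classes such as the 116 NK cells of HFD_EXE.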

Other observations

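The values of 5 genes that low oxygen can induce through HIF transcription factors were read after they had been seen, and no list of such genes was fixed or placed against others. In the LSEC class of S, HFD_sed and HFD_EXE, Ankrd37 was at 0.334, 18.3 and 0.904 CPM, Egln3 at 0.593, 43.2 and 0.937 CPM, Vegfa at 17.1, 49.1 and 13.8 CPM and Bnip3 at 29.0, 94.4 and 49.5 CPM. In neutrophils Egln3 was at 20.2, 74.0 and 20.9 CPM and Vegfa at 39.4, 145 and 30.1 CPM. Ndrg1 had another order, at 329, 347 and 766 CPM in LSECs. No explanation was tested for these values.

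The unnamed cluster 14 (61, 489 and 89 cells, with a median of 11569 UMIs over the libraries) was read gene by gene after its values were seen. Mmp12 was at 439, 602 and 426 CPM in S, HFD_sed and HFD_EXE, Cx3cr1 at 835, 331 and 514 CPM, Ccr2 at 510, 134 and 416 CPM, Trem2 at 259, 109 and 182 CPM, Gpnmb at 94.5, 86.4 and 9.56 CPM and Clec4f at 685, 909 and 349 CPM. Over all cells mt-Atp6 was at 55.8, 133 and 198 CPM, mt-Co2 at 8.12, 23.3 and 34.2 CPM and mt-Co3 at 18.9, 50.1 and 67.4 CPM, while mt-Co1 was at 1382, 1185 and 1308 CPM.

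Subtracting free RNA was among the alternatives fixed at the start, but its use as a test in the paragraphs that follow, and the tests on Slc15a2, Ide, handling and the clock, were chosen after the patterns were seen. The tests on free RNA and handling were first set for the classes together, decided nothing there, and were then read class by class. Ratios with both levels at or under 3 counts were left out after first results. Exercise, the diet, the animal, the dissociation and any batch share 1 library per group, so the data cannot separate them, and a biological explanation stays open and untested for each pattern.

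Single genes stood higher in HFD_sed than in S in each of the 9 compared classes other than hepatocytes. Slc15a2 was at 0.599, 42.1 and 4.41 CPM over all cells of S, HFD_sed and HFD_EXE. Its lower bound in HFD_sed was above the level that free RNA would give in 9 of 9 classes. In Kupffer cells, the closest of them, it was 22.3 against 13.8 CPM. For Slc15a2 this argues against free RNA at the estimated share as the source. Its 13 measured neighbours within 500 kb, taken from a GRCm38 annotation, had a median log2 ratio over all cells of 0.054 (highest 1.59, Ildr1). That is below the level set, after the pattern had been seen, for a change over the wider stretch. The differing class shares of the libraries can move such ratios, and a shorter stretch was not tested, so a change of the chromosome stays open. Ide was at 36.7, 70.2 and 83.8 CPM, with ratios to S over the classes of 1.48 to 2.57 in HFD_sed and 1.501 to 2.45 in HFD_EXE. A candidate explanation is a copy number difference, since a duplication of Ide and Fgfbp3 is known in this strain. The intervals held 2-fold in 6 of 9 classes in 1 HFD library and 7 in the other, with Fgfbp3 at 5.53, 8.82 and 10.5 CPM, so this stays open. An inherited difference between the animals may also underlie Slc15a2, and was not tested.

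The inflammatory list was lower in HFD_EXE than in HFD_sed in the 9 classes. With free RNA subtracted the median was −1.66 in LSECs (before, −1.22) and −0.997 in T cells over 9 genes (before, −1.23). There this argues against free RNA at the estimated share as the whole source. In B cells over 5 genes the median was 0.092 (before, −1.56) and in Kupffer cells 0.20 (before, −0.55). Free RNA may account for the values of both. A response to handling was tested by weighting the HFD_sed cells to the immediate early and heat shock share of HFD_EXE cells. By construction this brought the immediate early medians to between −0.08 and 0.03. The smallest group of T cells of HFD_sed so weighted held 16 cells. The inflammatory median then stayed at −1.05 in LSECs and −1.11 in T cells. There this argues against handling that follows this share of a cell as the whole source. At −0.44 in Kupffer cells and −0.45 in monocytes the median decides nothing. Inflammatory genes that respond to handling without following this share were not tested. In the other classes handling was not tested, and heat shock medians were lower in HFD_EXE in all 9. Medians stayed lower with free RNA subtracted in 7 of the 9 classes. A lower inflammatory state with exercise is a hypothesis that these tests do not decide. In LSECs and T cells they argue against free RNA at the estimated share as the whole source. They also argue there against handling that follows the immediate early and heat shock share. Other handling and other differences between the libraries stay open in each class.

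The glucocorticoid list was higher in HFD_EXE in the 9 classes. With free RNA subtracted the median was 1.29 in LSECs (before, 1.32), which argues against free RNA at the estimated share there. In T cells the median was 0.61 (spread 0.17; before, 0.73), which leaves free RNA open. In B cells it was −0.26 (before, 0.97), and free RNA may be the source. A difference in the time of collection would move the arms of the circadian clock apart, and 1 of 7 classes had them apart by at least 0.58 (monocytes, at 1.34; LSECs were at 0.55), which leaves that explanation open. Higher corticosterone with exercise, or with handling before collection, could give such values too, and neither was tested. Other differences in handling or cell state between the libraries were not tested for this list and stay open.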
